A study of Mus musculus with 4 samples.

How the data were processed

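Mouse granulocytes, HPC, LT-HSC and ST-HSC were each measured on 1 single-colour Affymetrix array, per the series design. Per the labels' protocols, granulocytes were sorted from bone marrow to a purity of 99.4% by morphology. The other 3 populations were enriched with c-Kit beads and sorted by c-Kit, Sca-1 and CD34 after exclusion of cells with Gr-1, CD11b, B220, CD3, CD4, CD8 or Ter119. Per the labels, cells were packed, 50 or 100 at a time, into empty zonae pellucidae (the emptied coats of eggs). RNA of 50 to 200 cells per type went through 2 rounds of linear amplification with aminoallyl labelling before biotin was coupled. Such amplification starts from the 3′ end of transcripts, so probe sets far from it lose signal, and from few cells it adds noise that differs between arrays.

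The deposited values are probe set intensity on a linear scale. The summary software, its version and detection calls are not given in the sources used here. The 2% trimmed mean of all probe sets was 500.00 on every array, so the arrays share 1 scale and the values were used as deposited. Of 45101 probe sets, 64 controls were left out and 45037 used. GEO's platform annotation gave 1 gene symbol for 34945, several for 932 and none that could be used here for 9160. Of those with 1 symbol, 34741 were found by Entrez number in the RefSeq annotation of the mouse assembly GRCm38.p6, which was used for names only. No symbol was updated through its Entrez number. No genome build applies to the values, and no coordinates are given.

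Values under the floor, the median of all values pooled over the arrays (120.1), were set to the floor before log2. A difference with 1 side at the floor is given as at least N-fold, and none is given where both sides lie there. A gene was represented by its probe set with the highest mean log2 value, which gave 18193 genes, 9010 of them with several probe sets. Where a gene is said to disagree, another of its probe sets above the floor had the opposite sign. There were 3 main comparisons: granulocytes against each of the other 3 arrays, HPC against each of the 2 stem cell arrays, and LT-HSC against ST-HSC. The size of a gene was its smallest log2 difference where all had 1 sign, and otherwise 0. Genes of at least 4-fold were counted in each direction. No test was possible with 1 array per cell type, and no p-value is given. The SD of differences between probe sets of 1 gene served as the yardstick of error.

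The gene lists, 22 of themes and 10 of markers of other cells the gates or the handling could hold, were fixed before the data were examined, as were the comparisons, the floor, the threshold and the rule for named genes. Of 594 list members, 44 had no probe set with a single symbol and were not analysed here. The themes were the sorting antigens, primary granule proteins, secondary and tertiary granule proteins, mature neutrophil genes, the phagocyte NADPH oxidase, stem cell genes, 3 kinds of progenitor, mitosis, DNA replication, quiescence, ribosomal proteins, oxidative phosphorylation, glycolysis, pluripotency, DNA and histone modifiers, remodelers and chaperones, imprinted genes, apoptosis, immediate early and heat shock genes and interferon-stimulated genes. The markers were those of B-lineage, T and NK, monocyte and macrophage, eosinophil, basophil and mast, megakaryocyte and platelet, mature erythroid, stromal and endothelial, oocyte and cumulus cells, with 1 sex-linked check. This check pooled Xist with Y-linked genes, which differ in opposite directions between the sexes, so its median cannot be read as a difference in sex. Cdkn1c and Ndn stand in both the stem cell and the imprinted list, and Csf1r in both the granulocyte-monocyte and the monocyte list. For each list the median log2 difference against the mean of the reference arrays was given. Its percentile was taken among 10000 random lists of the same size matched on mean expression in 20 bins. A list was said to stand apart at or under the 2.5th or at or above the 97.5th percentile. Of lists of randomly drawn genes, 5% would do so. Lists whose genes vary together on an array could do so more often without any difference between the cell types. Counts of list members use 2-fold against the same mean.

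Named genes were the 10 with the largest size in each direction of each comparison. Their higher side had to reach the array's 75th percentile, and their other probe sets above the floor had to have the same direction. Unnamed clones and predicted genes were passed over. Members of the lists with large and small differences were named as examples, with all sorting antigens. Some list members were named as further examples after their values had been seen, and so were Rag1 and Ccr9.

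Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The procedure was tested on simulated data for 18193 genes with 200 genes changed and noise of SD 0.5 log2 units. Of genes changed 8-fold, 81.5%, 89.0% and 91.0% passed the 4-fold threshold in the granulocyte, HPC and LT-HSC against ST-HSC comparisons, and of genes changed 4-fold 27.0%, 38.0% and 49.5%. At most 1, 4 and 45 unchanged genes passed. Of 100 unchanged lists, 6, 6 and 4 were called. The noise was chosen, not estimated from the arrays, and was independent between genes and arrays. The unchanged genes and lists called follow from that choice and do not estimate chance calls in the data. The changed genes and the members of these lists were drawn only from genes well above the floor. The shares recovered therefore do not cover genes near the floor.

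Alternatives fixed before the data were examined were quantile normalization, scaling to a common median or 75th percentile, no floor or a floor at the 25th or 75th percentile, the median over a gene's probe sets, its first probe set by name without the suffixes _x_at and _s_at, all probe sets with these suffixes left out, a filter on dim genes, thresholds of 2-fold and 8-fold, each array left out, the mean of the reference arrays, the list mean, and random lists not matched on expression. Scaling to the hybridization controls, which are spiked in at the same amount, and the lists without the LT-HSC array were chosen after seeing the data.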

Results

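Gene expression was measured on 4 single-colour mouse arrays, 1 each for granulocytes, haematopoietic progenitor cells (HPC), long-term repopulating haematopoietic stem cells (LT-HSC) and short-term repopulating haematopoietic stem cells (ST-HSC). Granulocytes, the mature and non-dividing end of the myeloid lineage, were sorted from bone marrow by high granularity and strong Gr-1 staining. The other 3 populations were enriched for the receptor c-Kit, depleted of cells with lineage antigens and divided by Sca-1 and CD34. HPC came from the Sca-1 negative gate, LT-HSC from the Sca-1 positive gate without CD34 and ST-HSC from the Sca-1 positive gate with CD34. The cells were of the kinds used as nuclear donors for cloning, and the arrays addressed whether each donor population had the profile of its cell type. Every array gave 45101 probe set signals, with medians of 132, 114, 120 and 114 for granulocytes, HPC, LT-HSC and ST-HSC. The highest signals were 68994, 46965, 40070 and 46692. Between 48.7% and 52.5% of the probe sets lay above the floor of 120.1, under which signals were treated as unmeasured. With 1 array per cell type, no difference has a replicate check, and the number of arrays limits the precision of every value. The only yardstick of error was the spread between probe sets of 1 gene. Its SD was 0.85 log2 units for the granulocyte comparison (2874 genes), 0.57 for the HPC comparison (3511 genes) and 0.64 for LT-HSC against ST-HSC (3875 genes). It covers neither the spread between sorts nor that between amplifications.

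The granulocyte profile lay far from the other 3, which lay close together. Of 18193 genes, 2353 were at least 4-fold apart between granulocytes and HPC, 2423 between granulocytes and LT-HSC and 2500 between granulocytes and ST-HSC. HPC and LT-HSC were 4-fold apart for 352 genes, HPC and ST-HSC for 383, and LT-HSC and ST-HSC for 341. Pearson correlations across genes ran from 0.725 to 0.746 for pairs with granulocytes and from 0.937 to 0.938 for the other pairs. Spearman correlations ran from 0.696 to 0.714 and from 0.894 to 0.903. Genes are not independent replicates, so these correlations only describe the arrays.

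The genes of the sorting antigens differed between the arrays as follows. Kit, which encodes c-Kit, had a signal of 583 in granulocytes and of 3011, 5416 and 3144 in HPC, LT-HSC and ST-HSC. Cd34 had 17.2 in granulocytes, 5190 in HPC, 2384 in LT-HSC and 9778 in ST-HSC, so the population sorted as CD34 negative had 4.10-fold less Cd34 signal than the CD34 positive one. Itgam, which encodes CD11b, had 2570 in granulocytes and 7.9 to 34.8, under the floor, on the other arrays. Ptprc, whose product CD45 includes the B220 form, was bright everywhere, at 21001 in granulocytes and 7066 to 9845 elsewhere. Cd4 lay under the floor on every array, Cd3e between 40.2 and 155 and Cd8a between 158 and 351. The genes for Sca-1 and Gr-1 were not analysed here. As a list of 7 measured genes the sorting antigens did not stand apart in any of the 3 comparisons, with medians of 0 for granulocytes, 0.10 for HPC and 0 for LT-HSC against ST-HSC.

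**Figure D1:**
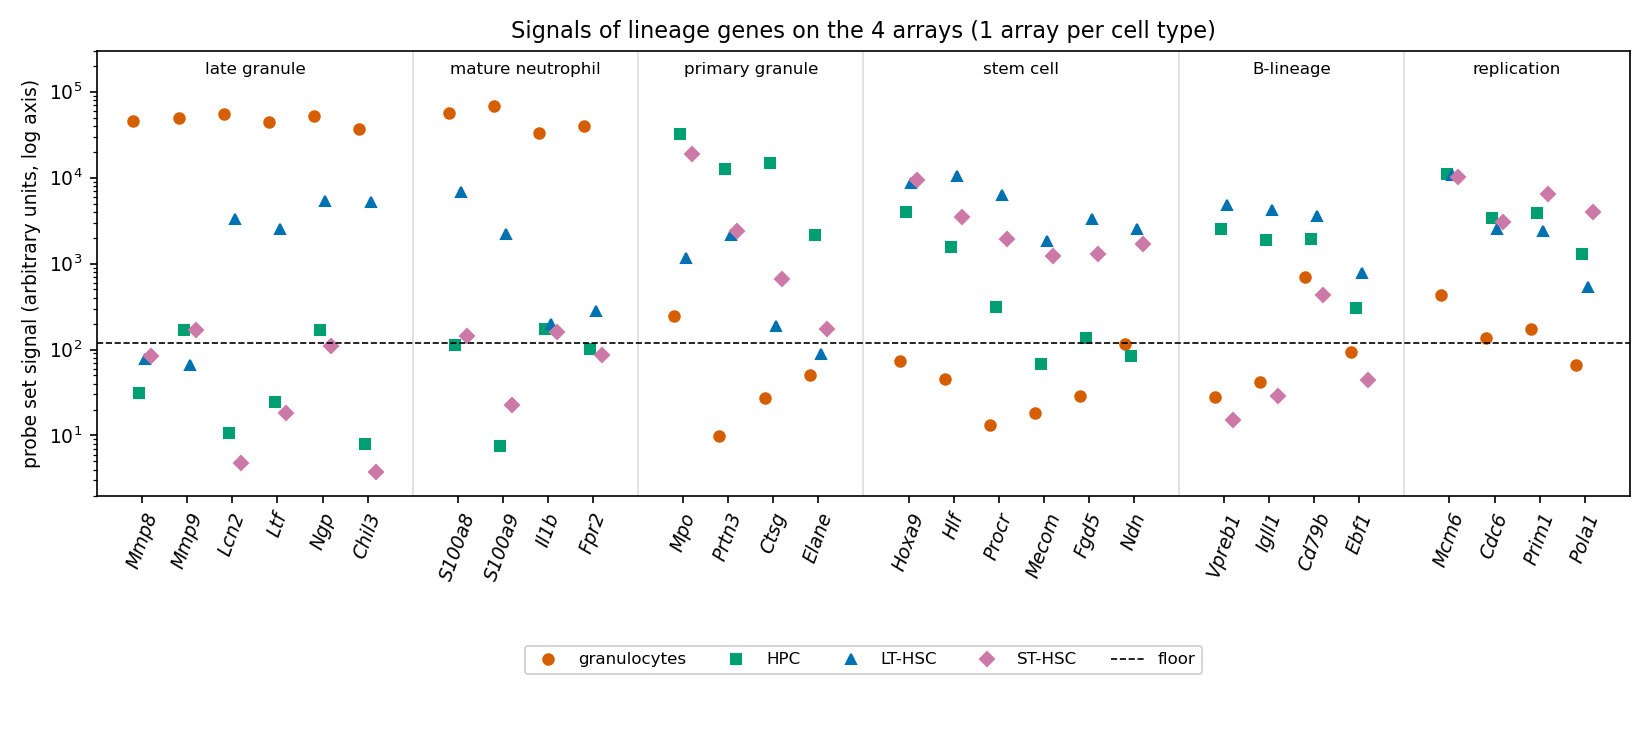
Probe set signal (log axis, arbitrary units) of genes from 6 fixed lists, with 1 point per array and the floor of 120.1 as a dashed line. Mmp8 reached 45533 in granulocytes and lay under the floor on the other 3 arrays, while Mcm6 lay at 434 in granulocytes and at 10124 or above elsewhere.

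Granulocytes were compared with HPC, LT-HSC and ST-HSC to see which genes set the differentiated donor cells apart from the stem and progenitor donors. Granulocytes had 507 genes at least 4-fold higher than each of the other 3 arrays, led by enzymes and receptors of mature neutrophils. They had 949 genes at least 4-fold lower, among which the genes of DNA replication formed the fixed list with the lowest median after the primary granule proteins. Mmp8, the neutrophil collagenase, had a signal of 45533 and was at least 379-fold higher, and Mmp9, a gelatinase of tertiary granules, was 288-fold higher at 48874. Stem cell genes were lower in granulocytes, and so were 18 of 30 chromatin remodelers and histone chaperones.

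The 10 largest higher genes went on from Mmp8 and Mmp9 to Ifitm6 (199-fold), Ceacam10 (at least 188-fold), Plbd1 (178-fold) and Il1b, the cytokine interleukin 1 beta (169-fold). Olfm4, a protein of specific granules, was at least 166-fold higher, Pilrb1 152-fold, the formyl peptide receptor gene Fpr2 143-fold and the chitinase-like Chil1 at least 139-fold. At the other end, Bms1, a factor of ribosome assembly, was about 157-fold lower in granulocytes, and Armcx2 was at least 110-fold lower. Dntt, the terminal transferase of early lymphoid cells, was at least 73.8-fold lower, from 8862 to 15859 on the other arrays. Fkbp1a was 66.1-fold lower and Fkbp3 about 48.9-fold lower, both of the FK506-binding family. The granulocyte signals of Bms1 (125) and Fkbp3 (129) lay just above the floor and under the highest absent bacterial control of that array (138), so their folds are uncertain. With other choices of probe set the log2 difference of Bms1 was as small as −2.51 and that of Fkbp1a −2.11. Cdk6, a kinase of the G1 phase, was at least 55.2-fold lower, and Dtymk, which makes thymidine diphosphate, at least 53.3-fold lower. Hadh, an enzyme of fatty acid oxidation, was at least 51.6-fold lower, Phgdh, the first enzyme of serine synthesis, 44.0-fold lower and Ctla2a at least 43.8-fold lower. Bms1, Armcx2, Dntt, Fkbp1a, Hadh and Phgdh rested on probe sets with the suffix _x_at or _s_at. Over the alternatives the log2 difference of Hadh was as small as −2.84, that of Dntt −3.49 and that of Armcx2 −4.55.

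Granule genes divided by the stage of neutrophil maturation at which they are known to be made. All 13 secondary and tertiary granule proteins were at least 2-fold higher in granulocytes than the mean of the other 3 arrays, with a median log2 difference of 7.06 (percentile 100 among random lists). Lcn2 (lipocalin 2) reached 55717, Ngp 52499, Camp (cathelicidin) 48337 and Ltf (lactoferrin) 44166, while Fcnb had the smallest difference, at 512 against 120 to 308. The list of primary granule proteins, which are made in promyelocytes, had 5 genes, among them Ms4a3, which does not encode a granule protein. Of these 5 genes, 4 were at least 2-fold lower than the mean of the other arrays, and the median was −3.35 (percentile 0.06). Only 2 were so against each of the other arrays. Prtn3 had 9.8 in granulocytes and 2164 to 12638 elsewhere, and Mpo (myeloperoxidase) had 246 in granulocytes, 32023 in HPC, 1149 in LT-HSC and 18718 in ST-HSC. Ctsg had 27.3 in granulocytes and 14683, 188 and 671 in HPC, LT-HSC and ST-HSC, and Elane 51.2 in granulocytes and 2181, 89.3 and 175, so the lower values of these 2 genes rested mostly on HPC.

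Genes of neutrophil function were higher in granulocytes almost throughout. Of 15 mature neutrophil genes, 14 were at least 2-fold higher (median 5.91, percentile 100). S100a9 had the brightest signal of the array at 68994, S100a8 had 57218 and the chemokine receptor gene Cxcr2 2113, against 28.1 to 43.8 elsewhere. Ptafr, at 216 against 70.3 to 122, stayed within 2-fold. All 5 measured genes of the phagocyte NADPH oxidase, which makes superoxide, were at least 2-fold higher (median 4.24, percentile 100), from Cybb at 14387 against 74.6 to 555 to Rac2 at 22564 against 2020 to 3817. Of 10 granulocyte-monocyte progenitor genes, 5 were higher and 2 lower (median 1.43, percentile 99.92). Fcgr3 had 17944 against 51.9 to 2163 and Csf2ra 4636 against 284 to 518, whereas Irf8 was lower at 653 against 2123 to 10505.

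Stem cell and cell division genes were lower in granulocytes. Of 30 stem cell genes, 22 were at least 2-fold lower and 1 higher (median −1.77, percentile 0). Tal1 had 95.7 in granulocytes and 3015 to 6345 elsewhere, Hoxa9 74.0 and 3961 to 9430, Hlf 46.0 and 1566 to 10387, and Gata2 121 and 2394 to 4953, while Prdm16 was higher at 422 against 107 to 182. With other choices of probe set the log2 difference of Hoxa9 was as small as −0.22, that of Kit −0.62 and that of Prdm16 0. DNA replication genes were lower in 20 of 24 cases and higher in none (median −2.95, percentile 0). The helicase gene Mcm6 had 434 against 10124 to 11163, the primase gene Prim1 175 against 2366 to 6383 and the origin licensing gene Cdc6 136 against 2503 to 3404, while Cdc45, at 919 against 568 to 1636, had the list's only mean difference above 0. Of 20 mitosis genes, 13 were lower and none higher (median −1.23, percentile 1.23), and once dim genes were left out the median was −1.31 but did not stand apart from random lists. The kinase gene Aurkb had 48.9 against 1447 to 2540 and Cdk1 110 against 1076 to 2204, while Cenpf, at 889, lay above LT-HSC and ST-HSC (382 and 428) and near HPC (876). Of 48 ribosomal protein genes, 30 were lower and 1 higher (median −1.27, percentile 0), such as Rps19 with 1817 against 16470 to 17296 and Rpl41 with 3637 against 24652 to 32518.

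Chromatin genes were lower in granulocytes as a group. Of 30 chromatin remodelers and histone chaperones, 18 were at least 2-fold lower and none higher (median −1.32, percentile 0.05). Npm1 had 1133 in granulocytes and 12244 to 18310 elsewhere, the histone chaperone gene Asf1a 460 and 5014 to 7326, and the heterochromatin protein gene Cbx1 153 and 2270 to 3143, while Hmgb2 was above all others at 12694 against 5195 to 8235. Of 40 DNA and histone modifiers, 20 were lower and 2 higher (median −1.03, percentile 0.23). Hdac2 had 209 against 3806 to 6442 and the histone methyltransferase gene Ezh2 628 against 2934 to 4407. Other choices of probe set took the log2 differences of Hdac2 and Cbx1 to 0 and that of Asf1a to −0.58. The 2 higher genes were Tet2, an oxidase of methylcytosine, at 5999 against 1079 to 1407, and Mbd2 at 5954 against 1328 to 2596 (a log2 difference of 0.55 under scaling to the hybridization controls). With the median over a gene's probe sets, the modifier list had a median of −0.34 and no longer stood apart. The pluripotency-associated list had a small positive median of 0.35 (percentile 99.95), with 3 of 23 genes higher, and this median was 0 under scaling to the hybridization controls. The list no longer stood apart under 4 of 14 alternatives, that scaling among them. Klf2 and Klf5 were among the higher genes, but the log2 difference of Klf5 was 0.41 with its first probe set by name. Pou5f1, Nanog and Sox2 lay under the floor on all 4 arrays.

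Response genes and markers of other cells gave a mixed picture. Of 14 interferon-stimulated genes, 8 were at least 2-fold higher and none lower (median 1.18, percentile 99.94), such as Usp18 at 638 against 48.3 to 123. Immediate early and heat shock genes had a median of 0.74 (percentile 98.3), but 5 of 15 were higher and 4 lower, and the list no longer stood apart with any other choice of probe sets (percentiles 95.4 to 97.4). The immediate early genes Fos (21297 against 926 to 5119) and Dusp1 (18843 against 1458 to 2240) were higher and the heat shock genes Hspa1a and Hspa1b (the latter 1072 against 7848 to 22133) were lower. Of 8 cumulus cell markers, 5 were higher (median 1.43, percentile 100), led by the activin subunit gene Inhba at 6566 against 31.7 to 459 and the prostaglandin synthase gene Ptgs2 at 1056 against 38.2 to 527, but the list no longer stood apart with the floor at the 75th percentile (median 0), nor once dim genes were left out, although its median was then larger (2.42, percentile 97.2). The log2 difference of Ptgs2 was 0.36 under scaling to the hybridization controls. Whether these transcripts came from cumulus cells or from the granulocytes themselves was not tested. Oocyte markers did not stand apart (median 0, 2 of 14 genes higher). Nor did the lists of multipotent and lymphoid-primed progenitors (median −0.85, 2 of 13 genes higher and 6 lower), megakaryocyte-erythroid progenitors (0, 17 genes), quiescence (0.62, 10 genes), glycolysis (0.52, 7 of 15 genes higher, but apart under 4 alternatives), apoptosis regulators (0.48, 18 genes) and imprinted genes (−0.02, 18 genes). Oxidative phosphorylation had a median of −0.18 with 8 of 77 genes higher and 14 lower. Apoptosis regulators, and T and NK markers as lower, stood apart under 2 alternatives each, and 6 further lists under 1 each. Among markers of other cells, medians were −0.70 for the B lineage (8 genes), 0 for T and NK cells (7), 0 for monocytes and macrophages (12, of which 5 were higher, and apart with the list mean of 1.07 or with dim genes left out, median 1.89), 0 for eosinophils, basophils and mast cells (9), −0.18 for megakaryocytes and platelets (8), 0 for mature erythroid cells (4), 0.48 for stromal and endothelial cells (9) and 0.54 for the sex-linked check (4).

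The low side lay at the floor for 101 of the 507 higher and 417 of the 949 lower genes, and other probe sets of the gene disagreed for 9 and 107. The lower genes made up 65.2% of both, against 82.1% (323 higher, 1486 lower) after scaling to the hybridization controls and 55.9% (626 higher, 793 lower) after scaling to a common 75th percentile, and with the median over a gene's probe sets the lower genes numbered 565. Over the alternatives the list medians ran from −5.17 to −1.91 for primary granule proteins, −2.85 to −0.92 for stem cell genes, 0.81 to 1.66 for granulocyte-monocyte progenitors, −1.84 to −0.68 for mitosis, −1.88 to −0.77 for remodelers and chaperones and −1.59 to −0.15 for modifiers. They ran from 0.57 to 1.81 for interferon-stimulated genes, 0.13 to 0.97 for immediate early and heat shock genes, 0 to 1.17 for pluripotency and 0 to 2.42 for cumulus markers.

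**Figure D2:**
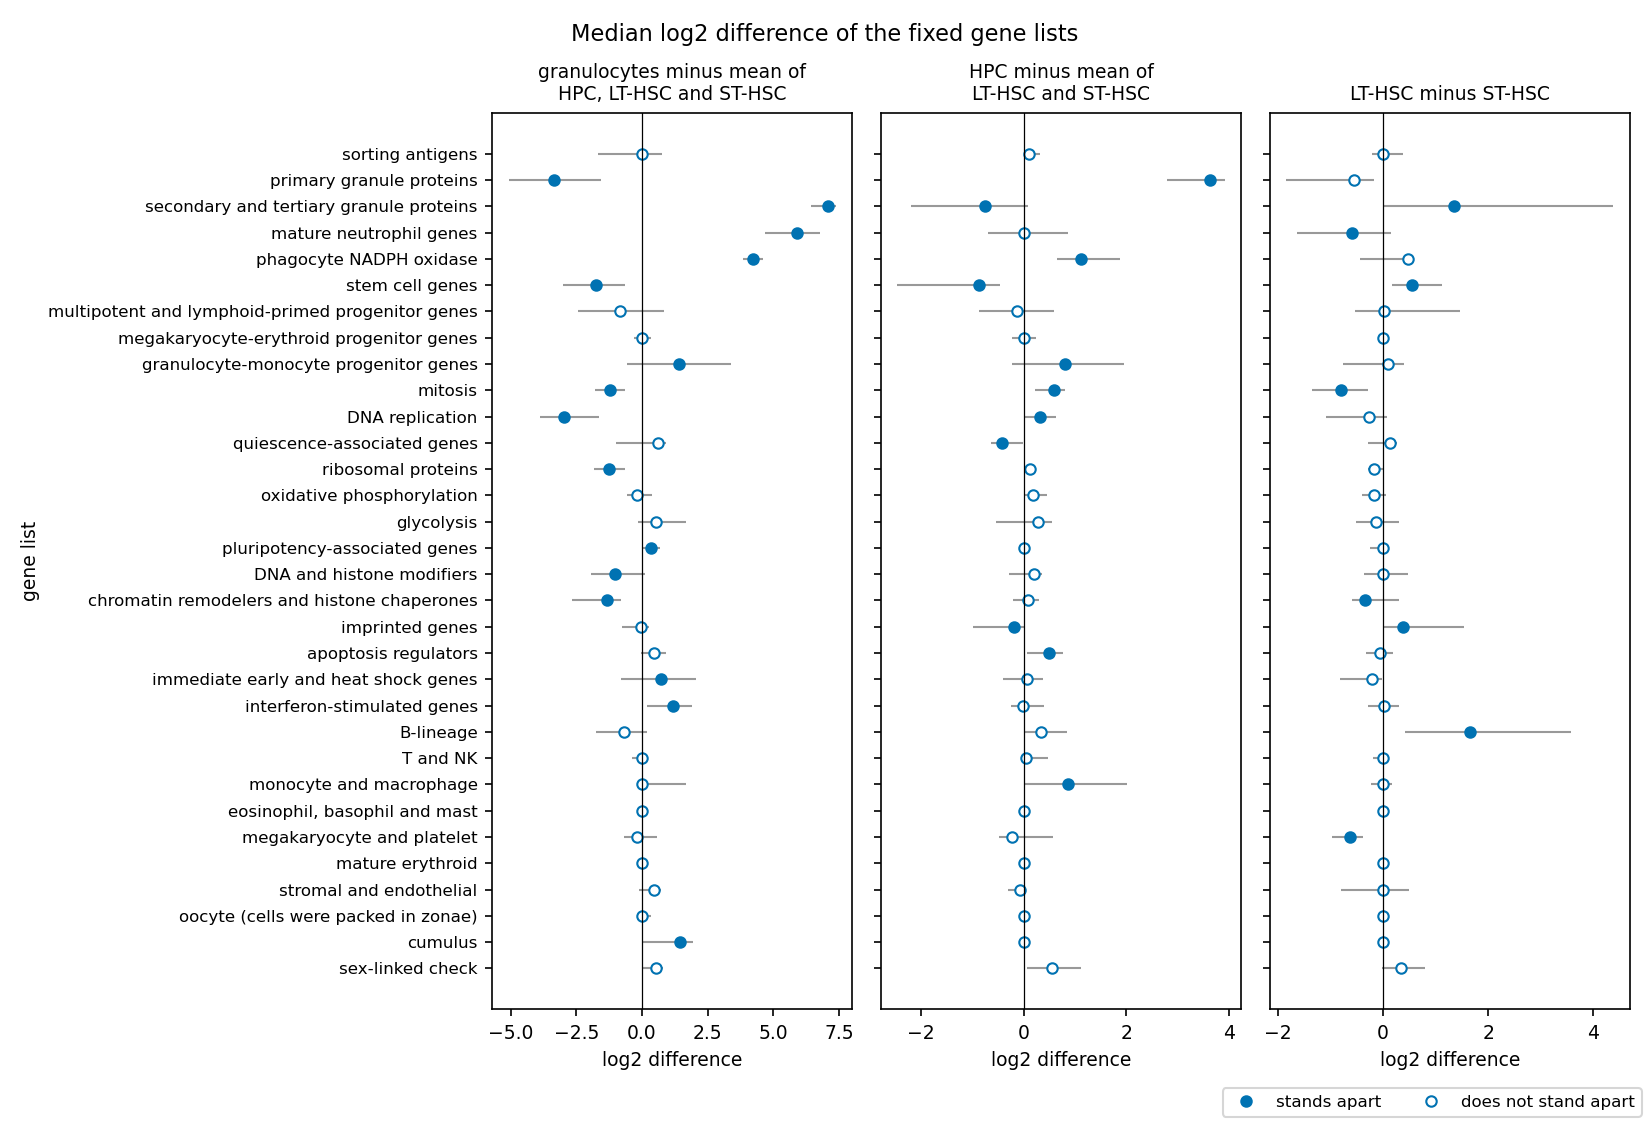
Median log2 difference of each fixed gene list in the 3 comparisons (filled points, lists that stand apart from random lists matched on expression; open points, lists that do not; bars, the quartiles over the list's genes). The widest separation is that of granulocytes, from −3.35 for primary granule proteins to 7.06 for secondary and tertiary granule proteins.

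HPC were compared with both stem cell arrays to see what distinguished progenitors from the Sca-1 positive stem cell gates. The difference was small in number, with 50 genes at least 4-fold higher and 60 at least 4-fold lower than on each stem cell array. Myeloid genes led the higher side, and the lower side included Ndn, Mecom and Fgd5, which are known from stem cells. The difference of Mecom rested on the choice of probe set. Csf1r, the receptor of macrophage colony-stimulating factor, was 22.8-fold higher in HPC, and the imprinted gene Ndn was at least 14.2-fold lower.

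Among the 10 largest higher genes, Ctsg (cathepsin G) was 21.9-fold higher and Elane (neutrophil elastase) 12.4-fold higher, both proteases of primary granules. Hp (haptoglobin) was at least 20.2-fold higher, the Fc receptor gene Fcgr3 17.4-fold, Acod1, which makes itaconate, at least 15.3-fold, and Tmem156 13.2-fold. Ly86 was 11.7-fold higher, Anxa3 11.6-fold and Igsf6 at least 11.3-fold. On the lower side, Tfr2 (transferrin receptor 2) was 11.7-fold lower, the noncoding RNA gene Malat1 11.4-fold, and Mecom, a transcription factor gene of long-term stem cells, at least 10.3-fold. Fgd5 was 9.38-fold lower, Ctnnal1 at least 8.23-fold, Plxdc2 at least 8.14-fold, Mctp2 at least 7.84-fold, Prxl2a 6.67-fold and Kctd18 6.43-fold.

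The primary granule, granulocyte-monocyte progenitor, NADPH oxidase and monocyte lists were higher in HPC, but those of late granule and mature neutrophil genes were not. All 5 genes of the primary granule list were at least 2-fold higher than the mean of the stem cell arrays (median 3.63, percentile 100). Mpo exceeded ST-HSC by less (32023 against 18718) than LT-HSC (1149). Prtn3 had 12638 in HPC and 2164 and 2425 in LT-HSC and ST-HSC, and Ms4a3 3372 against 372 and 200. Of 10 granulocyte-monocyte progenitor genes, 5 were higher and none lower (median 0.81, percentile 99.99), such as Irf8 at 10505 against 3320 and 2123 and Csf2rb at 6047 against 1970 and 1423, but with the first probe set of each gene by name the median was 0.40 (percentile 94.7) and the list did not stand apart. Of 5 NADPH oxidase genes, 3 were higher (median 1.12, percentile 100), including Ncf1 at 4621 against 1355 and 961. Monocyte and macrophage markers were higher in 6 of 12 cases (median 0.86, percentile 100), such as Cd14 at 1768 against 482 and 438 and Ms4a6c at 1560 against 461 and 250, although their median was 0 with the floor at the 75th percentile. The complement genes C1qa, C1qb and C1qc of mature macrophages lay under the floor on all arrays. The basophil and mast cell genes Mcpt8 (1096 against 10.5 and 126) and Cpa3 (1186 against 486 and 151) were also higher, but their list of 9 genes had a median of 0 and stood apart only with the list mean (0.44) or once dim genes were left out (median 2.13).

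Stem cell genes were lower in HPC in 13 of 30 cases and higher in 1 (median −0.87, percentile 0). Procr, the endothelial protein C receptor that marks stem cells, had 311 in HPC, 6229 in LT-HSC and 1931 in ST-HSC. Mllt3 had 88.6 in HPC against 1078 and 761, and Vwf 127 against 1097 and 499, while Gfi1b was higher in HPC at 868 against 478 and 268. Another 6 lists no longer stood apart without the LT-HSC array. Secondary and tertiary granule proteins had a median of −0.75 (5 of 13 lower, 1 higher), which was 0 against ST-HSC alone. Mitosis genes had a median of 0.59 (4 of 20 higher), and 0.14 against ST-HSC alone. DNA replication genes had 0.32 (4 of 24 higher) and 0.05, quiescence-associated genes −0.43 (1 of 10 lower) and −0.05, imprinted genes −0.18 (4 of 18 lower) and 0, and apoptosis regulators 0.50 (3 of 18 higher, 1 lower) and 0.39. The mitotic kinase gene Bub1 had 705 in HPC against 344 and 314, and the apoptosome gene Apaf1 1378 against 623 and 673. Without the LT-HSC array, 7 lists stood apart in place of 11 and included the B-lineage markers (median 0.94) and the sex-linked check (0.85).

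The remaining lists did not stand apart in HPC, though several did so under alternatives. The sex-linked check did so under 8, with a median of only 0.0012 when the median over a gene's probe sets was used. B-lineage markers and oxidative phosphorylation did so under 5 each, and T and NK markers under 2 (median 1.21 without a floor). Each of 4 further lists did so under 1. Medians were 0 for mature neutrophil genes (4 of 15 higher, 3 lower), −0.13 for multipotent and lymphoid-primed progenitors, 0 for megakaryocyte-erythroid progenitors, 0.13 for ribosomal proteins, 0.19 for oxidative phosphorylation, 0.29 for glycolysis, 0 for pluripotency-associated genes, 0.20 for DNA and histone modifiers and 0.09 for remodelers and chaperones. They were 0.06 for immediate early and heat shock genes, −0.01 for interferon-stimulated genes, 0.34 for B-lineage markers, 0.05 for T and NK cells, −0.23 for megakaryocytes and platelets, −0.07 for stromal and endothelial cells, 0.55 for the sex-linked check, and 0 for mature erythroid, oocyte and cumulus markers.

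Lower genes made up 54.5% of those past 4-fold in HPC, and 42.7% (63 higher, 47 lower) after scaling to a common 75th percentile. Without the LT-HSC array 197 genes were higher and 186 lower, and without the ST-HSC array 103 and 249. Over the alternatives the list medians ran from −1.39 to −0.58 for stem cell genes, 0.65 to 1.27 for NADPH oxidase genes, 0.40 to 1.38 for granulocyte-monocyte progenitors, 0 to 2.07 for monocytes and macrophages, −0.70 to −0.05 for quiescence, 0.17 to 0.65 for apoptosis, −0.97 to 0 for imprinted genes and −1.39 to 0 for secondary and tertiary granule proteins. Among the lower genes Malat1, Ctnnal1, Plxdc2, Prxl2a and Mecom rested on the choice of probe set, which took the first 4 to a log2 difference of 0 and Mecom to 0.37, and the same choice took Tfr2 to −0.66, Ndn to −1.27, Csf2rb to 0 and Ncf1 to 0.68.

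LT-HSC were compared with ST-HSC to see how the CD34 negative and CD34 positive stem cell gates differed. LT-HSC had 217 genes at least 4-fold higher and 124 at least 4-fold lower. The largest higher genes were late granule and neutrophil genes, also bright in granulocytes, and genes of early B cells. Stem cell genes were higher and mitosis genes lower in LT-HSC by smaller amounts. Mpo was 16.3-fold lower, at 1149 against 18718.

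The granule and neutrophil genes among the 10 largest higher were S100a8, 46.9-fold higher at 6783 against 145, Ngp (at least 44.1-fold), Chil3 (at least 43.8-fold), Lcn2 (at least 27.7-fold) and Ltf (at least 20.8-fold). The B-cell genes were Vpreb1 and Igll1, which encode the surrogate light chain of the pre-B cell receptor, at least 40.1-fold and at least 35.3-fold higher, and Pou2af1, a B-cell coactivator, at least 34.0-fold. Irf4 was at least 27.8-fold and the chemokine gene Ccl5 at least 26.7-fold higher. After Mpo, the largest lower genes were Slc25a15, a mitochondrial ornithine carrier (10.3-fold), the lectin receptor gene Clec4e (at least 9.62-fold), Nubpl (7.63-fold) and Pola1, the catalytic subunit of DNA polymerase alpha (7.53-fold). Zfp595 was 7.27-fold lower, Zc4h2 7.24-fold, the histone gene H3c4 at least 7.21-fold, Rad51ap1, a factor of recombination repair, 7.15-fold and Prmt6, an arginine methyltransferase, 7.15-fold.

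**Figure D3:**
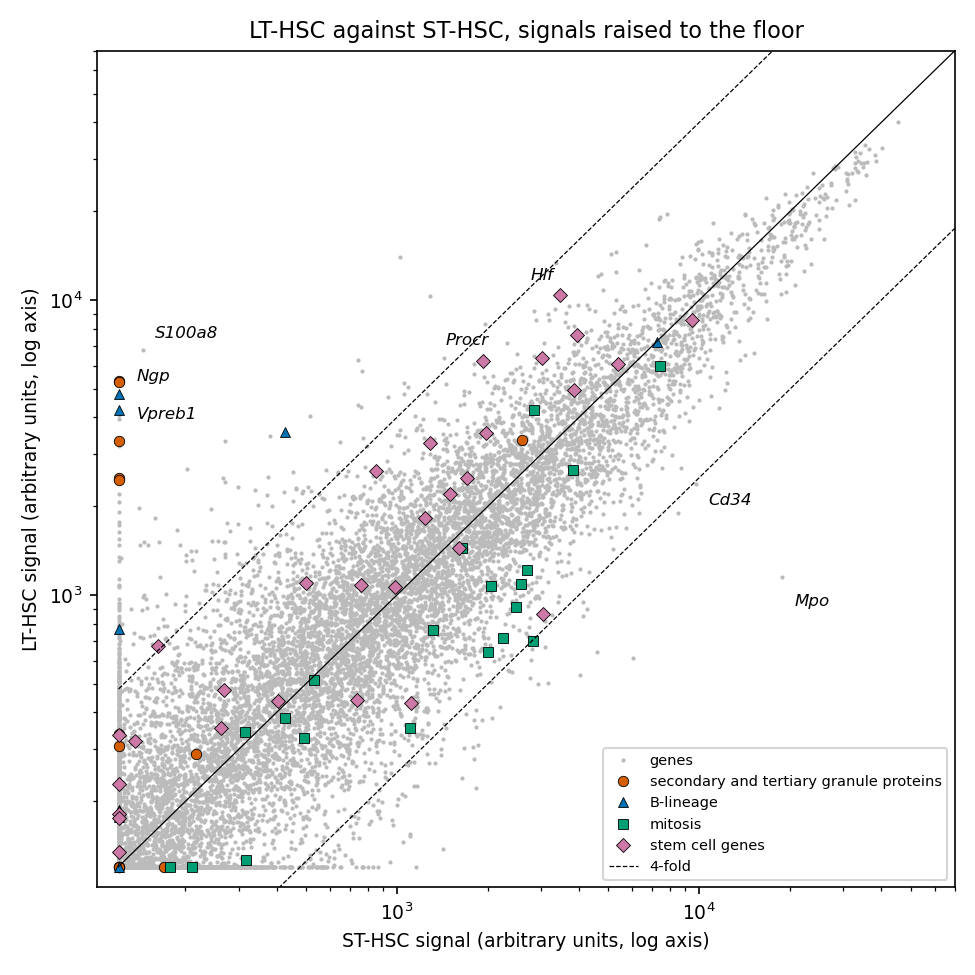
LT-HSC signal against ST-HSC signal of every gene (log axes, signals raised to the floor), with 4 fixed lists marked and dashed lines at 4-fold. Late granule genes such as Ngp and B-lineage genes such as Vpreb1 lie on the ST-HSC floor and at 5299 and 4815 on the LT-HSC array.

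Of 13 secondary and tertiary granule proteins, 7 were at least 2-fold higher in LT-HSC and none lower (median 1.36, percentile 100), although the median was 0 with the floor at the 75th percentile. Camp had 2451 against 54.7 in ST-HSC, 9.0 in HPC and 48337 in granulocytes, while Mmp8 (77.4) and Mmp9 (65.8) lay under the floor in LT-HSC. Mature neutrophil genes as a list were lower (median −0.58, percentile 0.39), with 5 of 15 lower and 3 higher, but their mean of −0.13 did not stand apart. Their median was 0 with the floor at the 75th percentile and with the median over a gene's probe sets. S100a9 was higher at 2203 against 22.9, and Csf3r (551 against 2404), Slpi (129 against 618) and Trem1 (128 against 563) were lower. B-lineage markers were higher in 4 of 8 cases and lower in none (median 1.66, percentile 100), and the median was 0.58 with the first probe set of each gene by name. Cd79b had 3562 against 428 and Ebf1 767 against 44.7, while Ighm did not differ (7223 against 7249). Pooled cells cannot show whether the granule and B-lineage transcripts came from all cells of the gate or from a few. On the HPC array, Vpreb1 had 2532, Igll1 1862 and Cd79b 1942. Rag1, the recombinase of lymphocyte receptor genes, had 2062 against 58.7 and the chemokine receptor gene Ccr9 1529 against 326, although the multipotent and lymphoid-primed list as a whole had a median of 0.02 (4 of 13 higher, 3 lower).

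Stem cell genes were at least 2-fold higher in LT-HSC in 9 of 30 cases and lower in 2 (median 0.56, percentile 99.97), with a median of 0.16 under the floor at the 75th percentile and 0.17 with the first probe set of each gene by name. Procr had 6229 against 1931, Hlf 10387 against 3458 and the adhesion gene Esam 2637 against 855, while Angpt1 (865 against 3047) and Mycn (430 against 1113) were lower. Imprinted genes were higher in 7 of 18 cases and lower in none (median 0.39, percentile 99.8), although the list did not stand apart without a floor (median 0.47, percentile 96.6) or with the floor at the 75th percentile (median 0), and its median was 0.06 with the first probe set by name. The adaptor gene Grb10 had 3325 against 271, the noncoding RNA gene Meg3 1965 against 243, Phlda2 631 against 104 and the cell cycle inhibitor gene Cdkn1c 673 against 163. The differences of Grb10 and Meg3 rested on the choice of probe set. Of 20 mitosis genes, 8 were lower and none higher (median −0.80, percentile 0, but −0.41 with the median over a gene's probe sets, where Ccna2 was within 2-fold). Examples were Ccna2 at 701 against 2822 and Mad2l1 at 713 against 2236, while Cdc20 had the largest positive difference at 4245 against 2847. Remodelers and chaperones had a median of −0.34 (percentile 0.89) with none of 30 genes past 2-fold. The list did not stand apart with the median over a gene's probe sets (−0.10), the first probe set by name (0) or the list mean (−0.19). Megakaryocyte and platelet markers were lower (median −0.62, percentile 0.98; 2 of 8 lower, 1 higher), and did not stand apart once dim genes were left out (median −0.46), with Pf4 at 472 against 1444 and Ppbp at 39.3 against 305.

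The other lists did not stand apart between the stem cell gates, though several did so under alternatives. Oxidative phosphorylation and immediate early and heat shock genes were lower under 3 each (the latter −0.49 with the median over a gene's probe sets), and DNA and histone modifiers higher under 2 (0.20 with that median), while 4 further lists stood apart under 1 each. DNA replication genes had a median of −0.27 (8 of 24 lower, 1 higher, the latter Ccne1 at 1512 against 269), but stood apart as lower under 7 alternatives, among them every other choice of probe set (medians −0.51 to −0.67). Primary granule proteins had a median of −0.54 and stood apart as lower under 5 alternatives, such as −0.97 without a floor. Medians were 0.48 for NADPH oxidase genes, 0 for megakaryocyte-erythroid progenitors, 0.09 for granulocyte-monocyte progenitors, 0.14 for quiescence, −0.16 for ribosomal proteins, −0.16 for oxidative phosphorylation, −0.14 for glycolysis and 0 for pluripotency-associated genes. They were 0.01 for DNA and histone modifiers, −0.05 for apoptosis regulators, −0.20 for immediate early and heat shock genes, 0.02 for interferon-stimulated genes and 0.34 for the sex-linked check. T and NK, monocyte and macrophage, eosinophil to mast cell, mature erythroid, stromal, oocyte and cumulus markers had medians of 0.

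The low side lay at the floor for 96 of the 217 higher and 33 of the 124 lower genes. Lower genes made up 36.4%, against 23.9% (300 higher, 94 lower) after scaling to the hybridization controls and 44.3% (175 higher, 139 lower) after scaling to a common 75th percentile. Over the alternatives the list medians ran from 0 to 2.12 for secondary and tertiary granule proteins, 0.42 to 3.28 for B-lineage markers, −0.69 to 0 for mature neutrophil genes and −1.08 to 0 for megakaryocytes and platelets. Other choices of probe set took the log2 differences of Slc25a15, Grb10, Ccr9, Trem1 and Mycn to 0, that of Igll1 to 0.60, of Ccne1 to 0.58, of Meg3 to −0.11, of Pola1 to −0.66, of Angpt1 to −0.81 and of Zfp595 to −0.88.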

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

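Scaling to the hybridization controls and the lists without the LT-HSC array were chosen only after the results were seen, and the other alternatives before. Under each of the 13 alternatives run for pairs of arrays, every pair with granulocytes had more genes apart than any other pair, while the order within the 2 kinds of pair did not always hold. Direction turned for 4 genes, each with another choice of probe set: Mecom (0.37) and Rsad2 (0.35) in HPC, and Meg3 (−0.11) and Kif11 (0.18, from −1.65) between LT-HSC and ST-HSC. Of the gene values under alternatives, 1782 of 2048 stayed within the probe set spread, 185 became smaller, 78 larger and 3 turned. Turned values were counted only for genes past 4-fold, so those of Kif11 are among the smaller. Lists that stood apart lost this under alternatives in 43 of 468 cases, none of them to the other side, and the other lists came to stand apart in 66 of 841. Of the 468 medians, 68 were smaller and 30 larger by more than 1.5 times. All 14 correlations that moved were lower, each under another floor. Where no cause is named, the cause was not tested.

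Other floors let in more or fewer low signals by their construction. Without a floor, granulocytes had 834 higher and 1588 lower genes, HPC 288 and 464, and LT-HSC against ST-HSC 1101 and 1025. With the floor at the 25th percentile, HPC had 129 and 192, and LT-HSC against ST-HSC 571 and 355. With the floor at the 75th percentile, granulocytes had 401 lower genes, HPC 25 higher and 11 lower, and LT-HSC against ST-HSC 63 and 30. For the pairs of granulocytes with HPC, LT-HSC and ST-HSC and then HPC with LT-HSC, HPC with ST-HSC and LT-HSC with ST-HSC, the genes apart numbered 4649, 5004, 4883, 2106, 2138 and 2126 without a floor. They numbered 3589, 3735, 3769, 944, 1037 and 926 at the 25th percentile and 1299, 1230, 1340, 126, 104 and 93 at the 75th. The mean correlation among the other 3 arrays exceeded that with granulocytes by 0.202, and by 0.180, 0.192 and 0.234 under these 3 floors.

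Thresholds act by their construction. At 2-fold, granulocytes had 1587 higher and 2288 lower genes, HPC 379 and 479, and LT-HSC against ST-HSC 1282 and 970, and the pairs in the same order 5834, 6040, 6054, 2142, 2273 and 2252. At 8-fold these were 240 and 361, 14 and 8, 45 and 5, and 978, 998, 1033, 80, 60 and 50. Against the mean of the reference arrays, a looser rule, granulocytes had 1456 lower genes and HPC 85 higher and 138 lower. With fewer arrays to differ from, HPC had 197 higher and 186 lower genes without the LT-HSC array and 103 and 249 without the ST-HSC array. With the median over a gene's probe sets, granulocytes had 565 lower genes.

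Scaling to the hybridization controls shifted the granulocyte comparison by −0.61 log2 units and gave 323 higher and 1486 lower genes. The other shifts above 0.1 were 0.11 (quantile normalization), −0.19 (common median) and 0.23 (common 75th percentile) for granulocytes, 0.15 (common 75th percentile) for HPC, and −0.11 (common 75th percentile) and 0.18 (hybridization controls) for LT-HSC against ST-HSC. In HPC, 7 lists stood apart without the LT-HSC array in place of 11, and between LT-HSC and ST-HSC 14 against lists not matched on expression in place of 8. With the floor at the 75th percentile 10 lists lost their call and 5 gained it, with the median over probe sets 7 and 7, with the first probe set 7 and 2, and without the LT-HSC array 7 and 3. Random lists not matched on expression gave 16 gained calls and none lost, and the list mean 10 and 3.

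Signal over background set the lower bound of what could be measured. Bacterial control probe sets with no transcript in the sample had medians of 12.4 to 19.3 and highest values of 52.5 to 138, near the floor of 120.1. Genes under the floor on both sides of a comparison could not be compared, and folds from the floor are lower bounds.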

Other observations

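Families of genes with a shared name were examined for differences outside the fixed lists, after the data had been seen. Of 242 families per comparison, 20 stood low and 15 high in granulocytes, and 11 and 14 in HPC. Between LT-HSC and ST-HSC 6 stood low and 11 high. Of lists of randomly drawn genes 5% would stand apart, and families whose genes vary together could do so more often. The directions given here held under all 4 other scalings. Toll-like receptors were higher in granulocytes in 8 of 9 cases (median 2.44, percentile 100), with Tlr2 at 23610 against 569 to 3197, Tlr13 at 3829 against 25.8 to 143 and Tlr4 at 941 against 29.9 to 157. Of 17 aminoacyl-tRNA synthetases 12 were lower (median −1.94, percentile 0.1), such as Iars at 11.7 against 3059 to 4534 and Eprs at 122 against 3993 to 6078, while Rars did not differ (2622 against 1783 to 3199). Nucleoporins named Nup were lower in 15 of 18 cases (median −1.88, percentile 0.1), such as Nup133 at 95.4 against 2235 to 4036. RNA polymerase subunits were lower in 15 of 25 cases (median −1.21, percentile 1), and genes named Eif, of translation initiation, in 23 of 46 (median −1.02, percentile 0.5), or in 19 (median −0.78) after scaling to a common 75th percentile.

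The Gimap family, GTPases known from lymphocytes, was brightest in LT-HSC. It was lower in granulocytes in 7 of 8 cases (median −3.02) and in HPC in 5 of 8 (median −1.21), and higher in LT-HSC than in ST-HSC in 4 of 8 (median 0.98). Gimap1 had 45.8, 1238, 3916 and 2165 in granulocytes, HPC, LT-HSC and ST-HSC, Gimap4 90.3, 981, 3470 and 382, and Gimap8 107, 388, 2376 and 1111.

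Further values in the order granulocytes, HPC, LT-HSC and ST-HSC were these. The 5′ probe set of 18S ribosomal RNA had 4677, 508, 16644 and 1333. The ratio of 3′ to 5′ signal was 5.75, 12.2, 14.6 and 16.1 for actin and 12.4, 17.8, 14.9 and 12.4 for Gapdh. The hybridization controls lay 0.46, −0.18, −0.23 and −0.05 log2 units from their mean over the arrays. Cd3d had 3890 in granulocytes and 14.6 to 206 elsewhere. The Y-linked Eif2s3y had 2635, 2395, 1866 and 827, and Xist 344, 160, 183 and 187.

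Of the tests weighed below, those on the 30 brightest genes, on both scalings for LT-HSC, on the choice of probe set and on the 3′ to 5′ ratio were chosen only after the results were seen, as was the interval around the share of lower genes. The scaling tests for LT-HSC at first took in other floors too, with lowest medians of 0 and 0.42 at the 75th-percentile floor. They were narrowed to scalings after that was seen, because a floor above most members sets differences to 0 by construction, and random lists later replaced the spread between probe sets as their yardstick. The test on the 3′ to 5′ ratio was later changed to ask for each of the 2 genes.

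Late granule genes were higher in LT-HSC than in ST-HSC, although the lineage cocktail held Gr-1 and CD11b, a gate that would remove granulocytes. Over the 10 genes of each list bright enough in granulocytes, the median implied share of granulocyte RNA was 53.4 times that of mature neutrophil genes (2.93% against 0.055%), but the quartiles overlapped (0.11 to 5.89 and −1.19 to 0.44) and S100a8 (11.6%) and Mmp8 (−0.016%) went against the split, so this did not decide. The lowest share of the 5 late granule genes at least 4-fold higher was 4.96%. At that share, 18 of the 30 brightest granulocyte genes lay more than 3-fold under the level needed. Examples were Mmp9 at 65.8 and Il1b at 199. Carry-over from granulocytes like those sorted was thus unlikely for these 5, if signals add linearly and carried-over cells had the average profile. Neither condition was tested. At the share of the less raised Cd177 (0.89%) only 4 of the 30 did, and for Cd177 carry-over stayed open. Scaling did not explain the pattern, since the scalings tried shifted this comparison by only −0.11 to 0.18 log2 units. The lowest list median over them was 1.14. Random lists of that size had an upper bound of 0.51 on the deposited scale. With 69.2% of the list above the floor in LT-HSC, expression by the stem cells and RNA from immature granulocytes both stayed open.

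B-lineage genes were higher in LT-HSC than in ST-HSC, and bright in HPC, although B220 in the cocktail would remove most B-lineage cells. Scaling, with the same small shifts, did not explain this (lowest median 1.49, against 0.48 for random lists on the deposited scale). The median was 0.58 with the first probe set by name and 0.62 without the suffixed probe sets. Of 12 further genes of pre-B cells 11 were above the floor, and 45.5% of these were at least 2-fold higher in LT-HSC. Of all 18193 genes, those under the floor included, 1282 were so. Among the 11, Blk (1151 against 164) and Akap12 (656 against 65.9) were higher, while Cd24a, the brightest, did not differ (13935 against 13614). RNA from B-cell precursors could therefore neither be shown nor ruled out.

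More genes were lower than higher in granulocytes. The lowest share of lower genes over the scalings was 55.9% (interval over genes 53.3% to 58.5%). With the median over probe sets the share was 54.4% (51.3% to 57.4%). These intervals treat genes as independent, which they are not, and cover no spread between arrays. Whether either choice made the majority of lower genes was not decided. The median over probe sets, however, took the lower genes from 949 to 565 and the higher genes only from 507 to 474. Scaling to a common 75th percentile gave 626 higher and 793 lower genes, and scaling to the hybridization controls 323 and 1486. The size of the excess thus depended on both the choice of probe set and the scaling. The mean log2 ratio of 3′ to 5′ signal in granulocytes differed from the lowest other array by −0.74, the opposite of what shorter amplified RNA would give. This came from actin alone, as the Gapdh ratio was 12.4 in both granulocytes and ST-HSC, so 2 genes left that explanation open.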
